A study of Rattus norvegicus with 2 samples.

How the data were processed

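Single-cell RNA-seq was run on fetal rat colon at embryonic day E19.5 in 2 libraries, 1 from a control pregnancy group (replicate 1) and 1 from a maternal obesity group (replicate 2). Per the labels' protocols, the tissue was digested with collagenase and pancreatic enzymes, filtered, treated to lyse red cells and loaded on a droplet instrument that tags each transcript with a unique molecular identifier (UMI). The labels do not give the number or sex of fetuses per library or the stretch of colon taken. The deposited values are raw UMI counts per gene and barcode in barcode-filtered matrices, with no normalisation by the authors. The submitters' processing notes name Cell Ranger 2.1.1 and the file headers name cellranger 6.1.2, so which version made the counts is open. The genome build is not given in the sources used here.

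Both matrices held 30400 gene identifiers with 28116 symbols, and the counts of the 2457 identifiers that share 173 symbols were added up per symbol. Of the 877 symbols in the marker and gene lists, 4 were matched through a RefSeq synonym and 49 were not analysed here, among them Sh2d6 and Kctd12 of the tuft markers, Lama3 of the laminins, Itgb5 of the integrins and Col1a2 and Col6a3 of the collagens. Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 6879 of 8903 barcodes in control and 7236 of 9714 in maternal obesity. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 barcodes. It called 49 cells (0.712%) in control and 153 (2.11%) in maternal obesity, against expected shares of 7.12% and 7.77%, so many doublets will have stayed. The calls passed a preset minimum of 0.5% and were removed, which left 6830 and 7083 cells.

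For clustering, counts were scaled to 10000 per cell and log transformed, 2000 variable genes among those seen in at least 10 cells were taken, and 30 principal components and 15 neighbours were used for Leiden clusters at resolution 1. No adjustment between libraries was made before clustering. Cells formed 34 clusters (C0 to C33), and cells of the epithelial-like clusters were clustered again into 19 (E0 to E18). Cluster names came from marker lists fixed before the data were examined. The rule that turned the lists into names was set after the clusters had been seen. A cluster took the name of the list with at least 2 markers among its 10 leading genes by fold, or else of the list with the highest mean log2 level over the other clusters. That mean had to reach 2 and lead the next list by 0.5, or reach 1.5 where at least 2 markers were among the leading genes, and at least 3 markers had to be higher. Clusters whose median UMIs lay under the library median divided by 3 with no own marker among the leading genes stayed unnamed, and so did a cluster led by haemoglobin genes with a low haemoglobin share. Epithelial sub-clusters needed at least 3 markers of a class among the 50 leading genes and at least 1 among the first 10. Sub-clusters led by another cell type's genes (at least 3 of its markers among 10 or 4 among 50) were set aside as mixed, and a sub-cluster led by defensin genes was left unnamed.

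UMIs were summed per gene, class and library and given relative to the class total of the library (CPM). With 1 library per group there is no test between groups, no p-value and no standard error. Ratios carry exact conditional binomial intervals, shares exact Clopper-Pearson intervals, and counts exact Poisson intervals, each at 95%. For a count of 0 the limit is that of 3 counts. Gene lists fixed before the data were examined are given as the median log2 ratio of maternal obesity over control (0.5 UMI added to both sums) over members with at least 20 UMIs, with the order-statistic interval of the median and the number of members at least 1.5-fold higher or lower. The percentile places a list's median among 10000 random lists of the same size, matched on mean expression in 20 bins. Shares of cells with marker UMIs were taken after thinning every cell to 3000 UMIs, with shallower cells left out, except where no thinning is stated. Where equal weighting is mentioned, log2 ratios were averaged over the 9 epithelial sub-clusters with at least 30 cells in each library.

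Named genes followed a rule fixed before the data were examined. In epithelial-like cells the 12 genes higher and the 12 lower in maternal obesity whose interval bound nearest 1 lay farthest from 1 were named among genes with at least 100 UMIs. In each other class with at least 50 cells in each library 3 genes each way were named, with a minimum of 20 UMIs where a class held under 300 cells in either library. Mitochondrially encoded, ribosomal, haemoglobin and sex-linked genes and identifiers without a symbol were left out of that ranking. The 3 members of each list with the highest CPM in the class described could also be named. Some genes that meet these rules are not reported here. HOX genes, Pitx genes and the RT1 family were looked at after the epithelial values had been seen.

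The steps were tested on simulated counts for the comparison of maternal obesity with control in epithelial-like cells, with 200 changed genes. Class sums were drawn from Poisson distributions, the model that the intervals assume. The values below therefore check the code. They do not show that the intervals hold for real UMIs, which can lie mostly in 1 cell. The interval of the ratio held the simulated value for 95.4% of 13192 unchanged genes. It excluded 1 on the right side for 82.4% of 68 genes changed 1.5-fold, 97.1% of 68 changed 2-fold and 100% of 64 changed 4-fold. All 24 genes named by the rule were changed genes on the right side, and the interval of the median held the simulated value in 194 of 200 lists of unchanged genes.

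Alternatives fixed before the data were examined were a mitochondrial limit of 10%, at least 1000 genes, doublets kept, Leiden resolution 2, ComBat adjustment of the libraries before clustering, median-ratio scaling, thinned cells, mean over cells' CPM, gene minimums of 1 and 100 UMIs, leaving out cells rich in haemoglobin or collagen UMIs, a denominator without erythroid and immune cells, and other limits for tuft-marker and cycling shares. Added after seeing the data were equal weighting of epithelial clusters, removal of the highest doublet scores at the expected share in both libraries, addition of low-UMI epithelial clusters, and a tuft count from 12 core genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used, with seed 1.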

Results

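Single cells of the fetal rat colon at embryonic day E19.5 were profiled in 1 library of the control group and 1 library of the maternal obesity group. The series title names tuft cells and signalling between extracellular matrix and integrins in the offspring's intestinal epithelium. The control library held 8903 barcodes with 103013814 UMIs (median 8599 per barcode) and the maternal obesity library 9714 barcodes with 120811946 UMIs (median 9142). After filtering, 6830 control and 7083 maternal obesity cells were compared. Haemoglobin genes took 11.5% of all UMIs in control and 20.7% in maternal obesity. There are no replicates, so every difference below is between 2 libraries, and intervals cover counting error only.

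The make-up of the whole colon differed most in the epithelium and the fibroblasts. Epithelial-like cells made up 37.8% of control cells (interval 36.6 to 39.0, 2581 cells) and 18.2% of maternal obesity cells (17.3 to 19.1, 1288 cells). Fibroblast-like cells were 5.97% in control (5.42 to 6.56) and 14.7% in maternal obesity (13.9 to 15.5). Subepithelial fibroblast-like cells, the layer directly beneath the epithelium, were 1.41% and 5.63%. Smooth muscle-like cells went the other way, at 12.1% in control and 8.75% in maternal obesity. Cells like interstitial cells of Cajal (ICC), the gut's pacemakers, were 5.77% and 7.68%, enteric neuron-like cells 5.01% and 6.21%, and enteric glia-like cells 4.17% in both libraries. Macrophage-like cells were 3.79% and 5.62%, lymphoid-like cells 1.27% and 2.54%, and erythroid-like cells 2.86% and 6.96%, after a red cell lysis step in the protocol that can set their number. Endothelium-like cells (0.571% and 0.480%) and mesothelium-like cells (1.03% and 0.678%) were scarce. Clusters without a name held 15.4% of control cells and 16.8% of maternal obesity cells, among them 2 low-UMI clusters with epithelial genes (174 and 179 control cells, 220 and 63 maternal obesity cells) and cluster C24 (86 and 368 cells), which had no clear marker list. Mixed sub-clusters held 1.90% and 0.819%. All shares depend on each other within a library and on how well each tissue layer came apart in digestion.

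**Figure D1:**
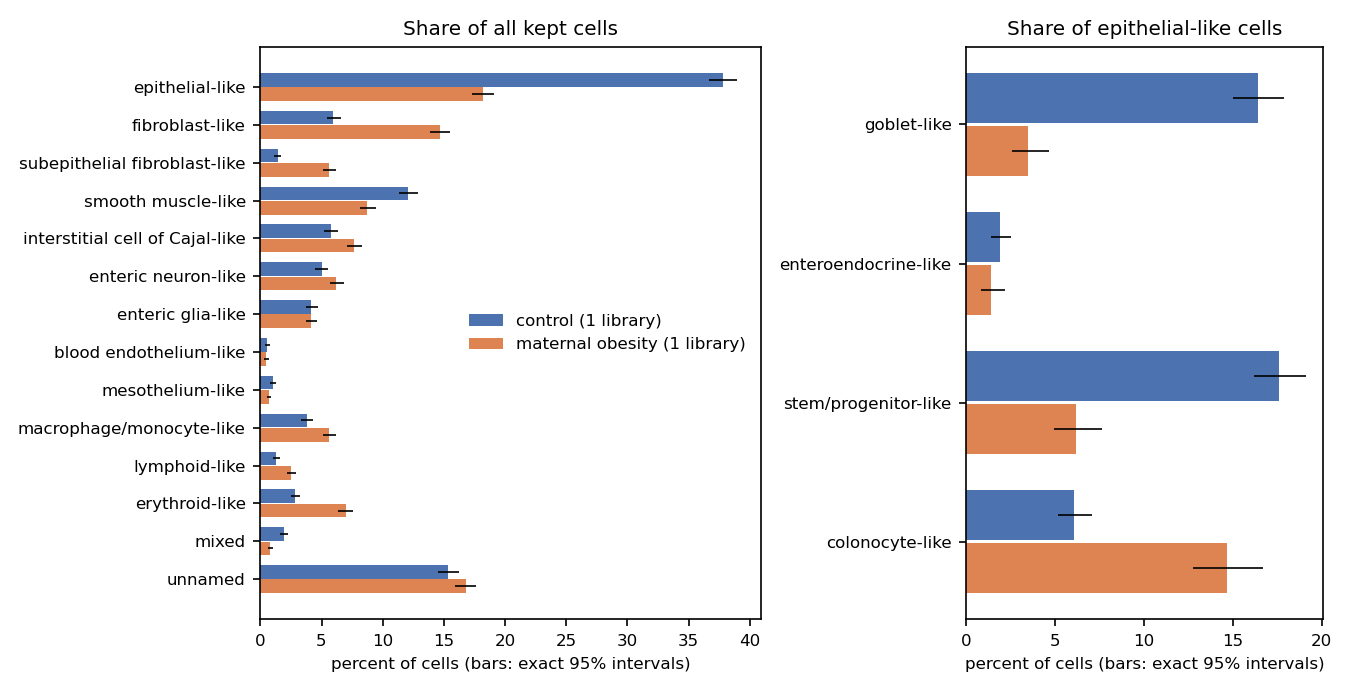
Share of all kept cells per class (left panel, percent) and share of epithelial-like cells per epithelial class (right panel, percent) in the control and the maternal obesity library, 1 library each, with exact 95% intervals as bars. Epithelial-like cells are 37.8% in control and 18.2% in maternal obesity, and goblet-like cells are 16.4% and 3.49% of epithelial-like cells.

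Within the epithelium the classes named goblet-like and stem/progenitor-like were a smaller share in the maternal obesity library, and the class named colonocyte-like a larger one. Goblet-like cells, which make mucus, were 16.4% of epithelial-like cells in control (15.02 to 17.91, 424 cells) and 3.49% in maternal obesity (2.56 to 4.65, 45 cells). Stem/progenitor-like cells were 17.6% (16.2 to 19.2, 455 cells) and 6.21% (4.96 to 7.67, 80 cells). Other settings kept both orders but moved the shares, at a mitochondrial limit of 10% to 31.5% and 6.09% for goblet-like and to 7.70% and 3.60% for stem/progenitor-like cells, which were 11.5% and 1.64% with ComBat adjustment. Colonocyte-like cells were 6.08% (5.19 to 7.08, 157 cells) and 14.7% (12.8 to 16.7, 189 cells). Enteroendocrine-like cells, which release gut hormones, were 1.90% and 1.398% (49 and 18 cells), a difference within counting error here, but 1.16% and 0.243% without the highest doublet scores. The unnamed, defensin-led cluster E5, which also has goblet markers, was 6.82% and 9.63%. The unnamed cluster E15, whose best list was stem/progenitor and whose first leading gene was Olfm4, went the other way from the stem/progenitor-like class. It was 0.891% in control and 2.096% in maternal obesity (23 and 27 cells), so the stem/progenitor-like difference depends on which clusters took the name. Goblet-like cells came from E3 (255 and 30 cells, with the immediate early gene Nr4a1 among its leading genes), E16 (105 and 13) and E13 (64 and 2), stem/progenitor-like cells from E0, enteroendocrine-like cells from E17, and colonocyte-like cells from E2, whose first leading genes were the embryonic haemoglobin genes Hbe1 and Hbz, with Alpi the only colonocyte marker among its 10 leading genes. The colonocyte-like name rests on these settings, since 6 of 7 alternatives gave no cluster of that name in both libraries.

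A count by marker genes, which uses the epithelial sub-clusters only to set mixed ones aside, gave the same order for cells with goblet markers. It holds many more cells than the goblet-like class (16.4% and 3.49%), so it is no count of goblet cells. After thinning to 3000 UMIs, which left out 135 control and 42 maternal obesity cells, 53.8% of control and 25.2% of maternal obesity epithelial-like cells had UMIs of at least 3 goblet markers. The share in fibroblast-like cells, which should lack them, was 4.51% and 1.11%. At least 2 colonocyte markers were seen in 56.5% and 60.0% (fibroblast-like 1.59% and 0.404%), and at least 2 stem/progenitor markers in 26.8% and 22.8% (16.5% and 16.6%). Median UMIs were 16661 and 24374 in epithelial-like cells and 7726 and 8533 in fibroblast-like cells. Several unnamed epithelial clusters came mostly from a single library, such as E11 (310 control and 20 maternal obesity cells, 12.01% and 1.55% of epithelial-like cells) and E1 (203 and 28, 7.87% and 2.17%). E4 (159 and 259) was 6.16% and 20.1%, and E5 held 176 and 124 cells. A cluster mostly of 1 library may be that library, not a type.

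No tuft-like cluster was found in either library. A few tuft cells could not form a cluster of their own, so this sets no limit on their share. The tuft cell master regulator Pou2f3, the cytokine gene Il25, the taste-pathway channel Trpm5, Rgs13 and Sh2d7 had 0 UMIs in the epithelial-like cells of both libraries. For Pou2f3, counted without thinning, this allows cells with a UMI up to a share of 0.116% in control (0 of 2581) and 0.233% in maternal obesity (0 of 1288). At 3000 UMIs per cell, at least 2 tuft markers were seen in 1.06% of control cells (26 of 2446; 0.696 to 1.55) and 0.722% of maternal obesity cells (9 of 1246; 0.331 to 1.37). Without thinning these shares were 17.9% and 26.8%. Thinned shares were 28.4% and 34.3% in fibroblast-like cells and 71.8% and 70.4% in macrophage-like cells (median 6851 and 7720 UMIs). These classes have UMIs of listed markers at such shares that they give no level of free RNA, and whether the epithelial shares are free RNA was not tested. Of a core set of 12 tuft cell genes, at least 2 were seen without thinning in 2 control cells (0.0775%) and 0 maternal obesity cells (limit 0.233%). These genes are not all confined to tuft cells, since Trpm5 had UMIs in 8.33% of control and 17.9% of maternal obesity fibroblast-like cells. Dclk1, often used as a tuft marker, had UMIs without thinning in 0.542% and 1.32% of epithelial-like cells and in 56.1% and 63.3% of fibroblast-like cells. Such unthinned shares also depend on depth, which was greater in maternal obesity. A comparison of tuft cells between the libraries, or of matrix and integrin genes within them, was not possible, since no group of tuft-like cells was found. Whether such cells were absent or their marker transcripts were missed was not tested.

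In epithelial-like cells the genes with the largest excess in maternal obesity included enzymes and transporters of absorptive cells. Cps1, the first enzyme of the urea cycle, was at 0.398 CPM in control and 16.8 CPM in maternal obesity (42.3-fold higher, 27.4 to 68.7). The aldo-keto reductase gene Akr1b8 was at 7.12 and 150 CPM (21.1-fold, 18.97 to 23.43), the brush border peptidase gene Enpep at 3.83 and 31.0 CPM (8.09-fold, 6.96 to 9.44), and the amino acid transporter gene Slc7a9 was 11.2-fold higher (8.15 to 15.8). Ccl25, a gut chemokine, was at 1.12 and 16.9 CPM (15.1-fold, 11.6 to 20.1) and Reg4, a secreted lectin, at 1.55 and 21.1 CPM (13.6-fold, 10.8 to 17.3). Also higher were the defensin gene Defa24 (35.6-fold, 14.9 to 111, with 32.8% of its UMIs in 1 cell), the interferon-inducible Rtp4 (18.7-fold, 11.1 to 34.1), the neurturin receptor gene Gfra2 (13.9-fold, 9.09 to 22.0), the transcription factor gene Gata5 (9.12-fold, 5.97 to 14.5), the basement membrane gene Nid2 (8.26-fold, 6.05 to 11.5) and the protease gene Capn3 (8.30-fold, 5.42 to 13.2).

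Genes with the largest deficit in maternal obesity were of several kinds. The microtubule-associated Map7d2 was at 12.4 CPM in control and 0.180 CPM in maternal obesity (68.9-fold lower, 33.2 to 172). Sftpd, which encodes surfactant protein D, was at 174 and 18.8 CPM (9.28-fold lower, 8.60 to 10.0), the immune checkpoint gene Vtcn1 at 21.4 and 1.52 CPM (14.1-fold lower, 10.8 to 18.6), and the class I histocompatibility gene RT1-A1 at 52.2 and 6.25 CPM (8.36-fold lower, 7.33 to 9.57). The tachykinin receptor gene Tacr3 had 145 UMIs in control and 0 in maternal obesity. Lower too were the squamous epithelial genes Sprr1a (36.4-fold, 17.5 to 91.3) and Krt4 (19.1-fold, 9.06 to 48.1), the intermediate filament gene Des (8.72-fold, 7.35 to 10.4) and the posterior patterning gene Hoxd12 with 129 and 3 UMIs (31.7-fold, 10.6 to 156). The ghrelin gene Ghrl (49.7-fold lower, 31.7 to 82.8) had 1281 UMIs in 51 control cells, of which 35.2% lay in 1 cell. All 306 control UMIs of the somatostatin gene Sst (3 in maternal obesity; 75.2-fold lower, 25.5 to 367) and 91.7% of the UMIs of the eosinophil gene Prg2 (132 and 1; 97.3-fold lower, 17.2 to 3871) came from 1 cell each. Over all classes, 22 of the 90 named genes had most of their UMIs in 1 cell.

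Equal weighting of the 9 shared sub-clusters, chosen after the data were seen, left some of these differences large, made others smaller and took some away. Akr1b8 stayed at a log2 ratio of 4.00, Map7d2 at -5.00, Vtcn1 at -3.33, Sftpd at -3.24 and RT1-A1 at -2.72. Cps1 remained higher but fell to 2.83, from 5.401 in the pooled cells. Ghrl was then at -1.0, Des at -0.73, Hoxd12 at -0.74 and Krt4 at -0.72. Sst (0.57) and Prg2 (0.17) then had the other sign. Among ribosomal protein genes, which the ranking left out, Rpl8 was at 4.78 (higher in 9 of 9 clusters) and Rpl30 at 1.08. Rps2 was at -0.73 (higher in 0 of 9), while Rpl10 was at 0.03 and Rps3 at -0.05. The cause of these differences was not tested.

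**Figure D2:**
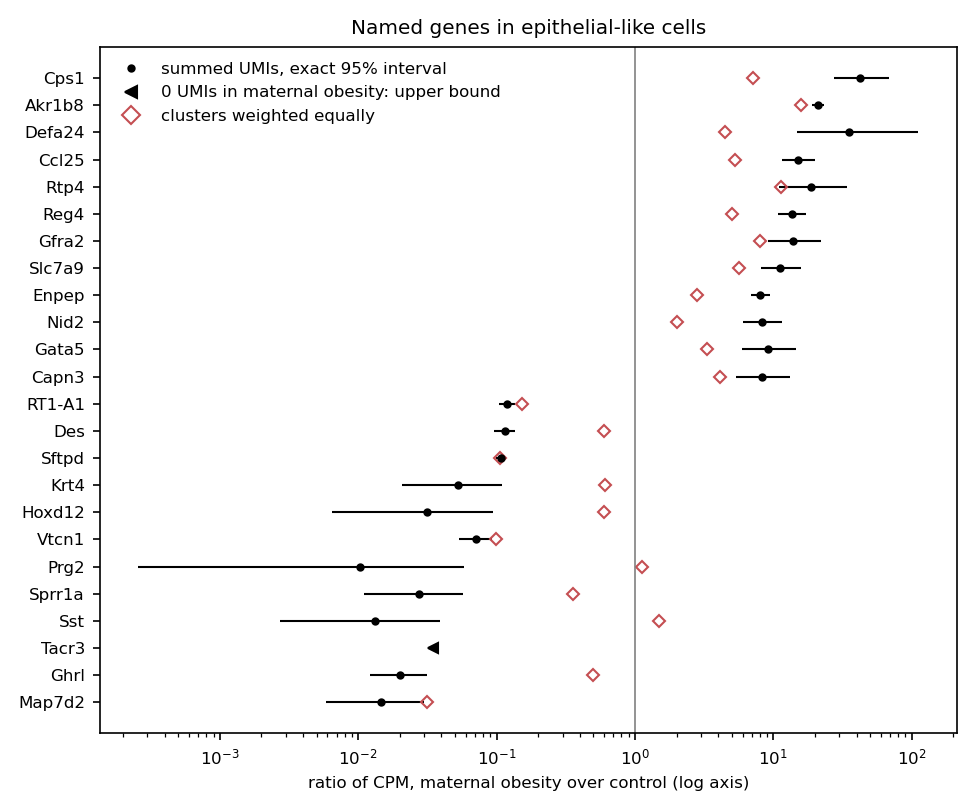
Ratio of CPM in maternal obesity over control (log axis) for the 24 named genes in epithelial-like cells, from 1 library each. Black points are ratios of summed UMIs with exact 95% intervals, the triangle is the upper bound for Tacr3 with 0 UMIs in maternal obesity, and open diamonds are the ratios with 9 clusters weighted equally. Sftpd keeps its ratio with equal weights, while Sst and Prg2 move to the other side of 1.

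Matrix and integrin genes, which the series title points to, showed no common direction in epithelial-like cells. The collagen list had a median log2 ratio of 0.34 (-0.18 to 0.61), with 5 of 17 measured members at least 1.5-fold higher and 1 lower (percentile 91.7 of random lists). Laminin and basement membrane genes had a median of 0.08 (-0.62 to 0.37; 2 higher and 4 lower of 15), other matrix glycoproteins 0.40 (-0.60 to 0.71; 4 and 4 of 16, percentile 98.6), matrix enzymes -0.10 (1 higher and 5 lower of 17) and integrin subunits -0.03 (-0.34 to 0.88; 3 and 2 of 13, percentile 26.5). The laminin gene Lama5 was 1.54-fold lower. Itgb1, the common beta subunit, was at 224 and 220 CPM, Itga6 at 27.8 and 29.4 CPM, and Itgb4, its hemidesmosome partner, at 57.9 and 45.6 CPM. Among collagens Col4a1 of the basement membrane was at 17.5 and 15.04 CPM and Col5a1 at 7.60 and 10.5 CPM, while the secreted Postn was 1.33-fold higher and Sparc 1.52-fold lower. With clusters weighted equally Itgb4 (0.33) and Postn (-0.38) had the other sign. Genes that act downstream of integrins had a median of -0.003 (2 higher and none lower of 30) and Hippo pathway genes -0.11 (3 and 2 of 11).
The non-integrin matrix receptors had a median of -0.09, with 1 of 8 higher and 1 lower. In epithelial-like cells Col1a1, a fibroblast gene, lay at 0.0729% of its fibroblast-like level in control and 0.0515% in maternal obesity, a measure of free RNA.

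Within the epithelial classes no integrin median stood clear of 0. In colonocyte-like cells, where the median of all genes was shifted by 0.15, integrin subunits had a median of 0.47 (-0.04 to 1.62; 4 higher and 0 lower of 8) and laminins -0.11. In stem/progenitor-like cells integrins were at 0.19 (-0.40 to 0.49, 10 measured), laminins at 0.05 (11 measured) and collagens at 0.44 (1 higher and 0 lower of 5). In goblet-like cells integrins were at -0.12 (-1.11 to 0.60, 2 higher and 2 lower of 9) and laminins at -0.05 (7 measured), and both were positive when the libraries were adjusted before clustering. These lists hold few members and rest on 45 goblet-like and 80 stem/progenitor-like cells in maternal obesity.

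Cell type and growth genes also differed between the libraries in epithelial-like cells. Goblet genes had a median of -1.18 (-1.38 to -0.63; 12 lower and 2 higher of 15, percentile 0.0), with the mucus-folding gene Agr2 at 3351 and 1723 CPM and the trefoil peptide gene Tff3 at 2440 and 1317 CPM. Within goblet-like cells the same list was at 0.08, and with clusters weighted equally it was at -0.28, with Agr2 at 0.05. Colonocyte genes had a median of 0.58 (-0.32 to 1.38; 7 higher and 3 lower of 15, percentile 100), lipid genes 0.26 (11 and 2 of 32, percentile 99.7) and stem cell and Wnt genes 0.25 (5 and 2 of 18). Enteroendocrine genes had a median of -0.28 (3 and 5 of 14), although the most abundant, the proglucagon gene Gcg, was at 124 and 344 CPM. Proliferation genes were at 0.39 (0.25 to 0.48; 2 higher and 0 lower of 20, percentile 100), and imprinted genes at 0.46 (4 and 2 of 10), led by the fetal growth factor gene Igf2 at 358 and 644 CPM. With the clusters weighted equally the proliferation median was -0.02, Igf2 was at 0.14 and Gcg at 0.42. Haemoglobin genes, a mark of free RNA, were at 2.29 (7 of 7 higher).

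Unfolded protein response and glycolysis genes were lower on balance in epithelial-like cells pooled, and immune lists were mixed. Unfolded protein response genes had a median of -0.43 (-0.52 to -0.22; 0 higher and 4 lower of 17, percentile 0.0), with the chaperone genes Hspa5 1.25-fold and Hsp90b1 1.24-fold lower. Within classes it was nearer 0, at 0.01 in colonocyte-like, -0.11 in goblet-like, -0.08 in enteroendocrine-like and -0.18 in stem/progenitor-like cells, and with clusters weighted equally Hspa5 was at -0.03. Dissociation and immediate early genes, a sign of handling, were at -0.29 (1 and 8 of 22), with Btg2 1.85-fold lower, but at 0.46 (5 and 2 of 19) in colonocyte-like and -0.04 in goblet-like cells. The inflammatory list had a median of -0.38 (5 higher and 7 lower of 23) but a mean of 0.04, with Nfkbia 1.51-fold and Cxcl10 1.90-fold lower and Ccl20 1.57-fold higher. With clusters weighted equally its median was 0.05, Nfkbia was at -0.26, Cxcl10 at -0.07 and Ccl20 at 0.20. In colonocyte-like cells the inflammatory list was at 0.33 (3 and 0 of 10) and interferon genes at 0.68 (6 and 1 of 10). Genes of type 2 immunity, the response in which tuft cells act, were at -0.46 (2 and 4 of 9), with the goblet cell gene Retnlb 2.34-fold and the receptor gene Il13ra1 2.54-fold lower (-0.67 and -0.36 with clusters weighted equally). The list was at 0.02 in goblet-like cells. Glycolysis genes were at -0.21 (0 and 5 of 23), TGF-beta genes at -0.30 (0 and 3 of 13) and cholesterol genes at -0.15 (1 and 2 of 22). Medians near 0 were seen for interferon genes (0.03; 3 and 5 of 26; mean -0.22), oxidative phosphorylation (-0.07), insulin and IGF genes (-0.03), Notch genes (-0.10), BMP and hedgehog genes (-0.09) and junction genes (-0.11). Mitochondrially encoded genes had a median of 0.32 (3 and 0 of 13), which was -0.01 as a mean over cells and 0.52 with clusters weighted equally. They were at 0.77 (7 and 0 of 13) in colonocyte-like, 0.54 in goblet-like and 0.22 in stem/progenitor-like cells.

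Cycling cells were more frequent among epithelial-like cells of the maternal obesity library but not within each class. At 3000 UMIs per cell, 53.4% of control and 69.3% of maternal obesity epithelial-like cells had at least 2 cycling genes (74.6% and 89.2% without thinning). In stem/progenitor-like cells the shares were 90.1% and 89.5%, in goblet-like cells 16.8% and 17.5%, and in colonocyte-like cells 78.4% and 83.2%. Fibroblast-like cells were at 60.7% and 59.7%, smooth muscle-like cells at 62.5% and 56.8% and ICC-like cells at 26.4% and 32.2%. The order in stem/progenitor-like and colonocyte-like cells turned with other limits.

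Stem/progenitor-like cells of the maternal obesity library had less of the neutrophil chemokine gene Cxcl3 (11.1-fold, 7.09 to 18.6), of Vtcn1 (8.82-fold, 4.22 to 22.2) and of Msln (98 and 1 UMIs, 24.1-fold, 4.23 to 962). The defensin genes Defa8, Defa9 and Defal1 were the genes with the largest excess there, but 75.0%, 57.5% and 100% of their UMIs lay in 1 cell each. In colonocyte-like cells Akr1b8 was 41.6-fold (21.7 to 91.5), Cps1 16.8-fold (7.50 to 46.7) and Meltf 11.8-fold (7.23 to 20.6) higher. Map7d2 (81 and 1 UMIs, 96.3-fold, 16.8 to 3851) and the secretory lineage factor gene Spdef (39 and 2 UMIs, 23.2-fold, 6.004 to 198.2) were lower there, and all 70 control UMIs of Neurog3 lay in 1 cell. Colonocyte genes had a median of 0.56 (6 higher and 1 lower of 12) and lipid genes 0.60 (15 higher and 0 lower of 28, percentile 100) in these cells, with haemoglobin genes at 3.90. All-gene medians over 0.1 in size were 0.15 in colonocyte-like, -0.11 in enteroendocrine-like, 0.12 in smooth muscle-like, 0.15 in ICC-like and -0.75 in erythroid-like cells.

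Collagen genes had positive medians in the mesenchymal classes, while other matrix lists differed by class. Fibroblast-like cells came from C2, led by matrix genes such as Dcn and Lum (144 of 408 control and 485 of 1039 maternal obesity cells), C17 (147 and 318) and C32 (117 and 236). In these cells collagens had a median of 0.60 (0.37 to 0.74; 10 higher and 0 lower of 20, percentile 100) and other matrix glycoproteins 0.71 (0.54 to 0.93; 17 and 1 of 25). Col1a1 was at 3169 and 5295 CPM, Col3a1 at 3510 and 5125 CPM, and the small proteoglycan genes Dcn and Lum were 2.02-fold and 2.20-fold higher. In subepithelial fibroblast-like cells collagens were at 0.73 (0.38 to 1.28; 10 and 0 of 16) and laminins at 0.65 (7 and 0 of 12), with the basement membrane gene Nid1 at 321 and 615 CPM. Smooth muscle-like cells, from C12 (464 of 825 control and 256 of 620 maternal obesity cells), C13 (120 and 205) and C14 (241 and 159), had collagens at 0.28 (4 and 0 of 16), laminins at 0.36 (6 and 0 of 15) and integrins at 0.39 (6 and 0 of 13). Other matrix glycoproteins were at 0.01 there (-0.24 to 0.66; 7 and 3 of 23), below the all-gene shift of 0.12. ICC-like cells had collagens at 0.39 (5 and 0 of 19), laminins at 0.59 (7 and 1 of 14) and integrins at 0.58 (4 and 0 of 9), with the integrin subunit gene Itga8 at 52.7 and 118 CPM. Mitochondrially encoded genes, which also depend on cell quality, had medians of 0.54 in fibroblast-like, 0.34 in subepithelial fibroblast-like, 0.50 in smooth muscle-like and 0.46 in ICC-like cells. In fibroblast-like cells integrins were at 0.11 (5 higher and 2 lower of 14) and contractile genes at -0.38 (0 and 3 of 16). The intestinal smooth muscle actin gene Actg2 was at 27571 and 21026 CPM in smooth muscle-like cells, where contractile genes had a median of -0.20.

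**Figure D3:**
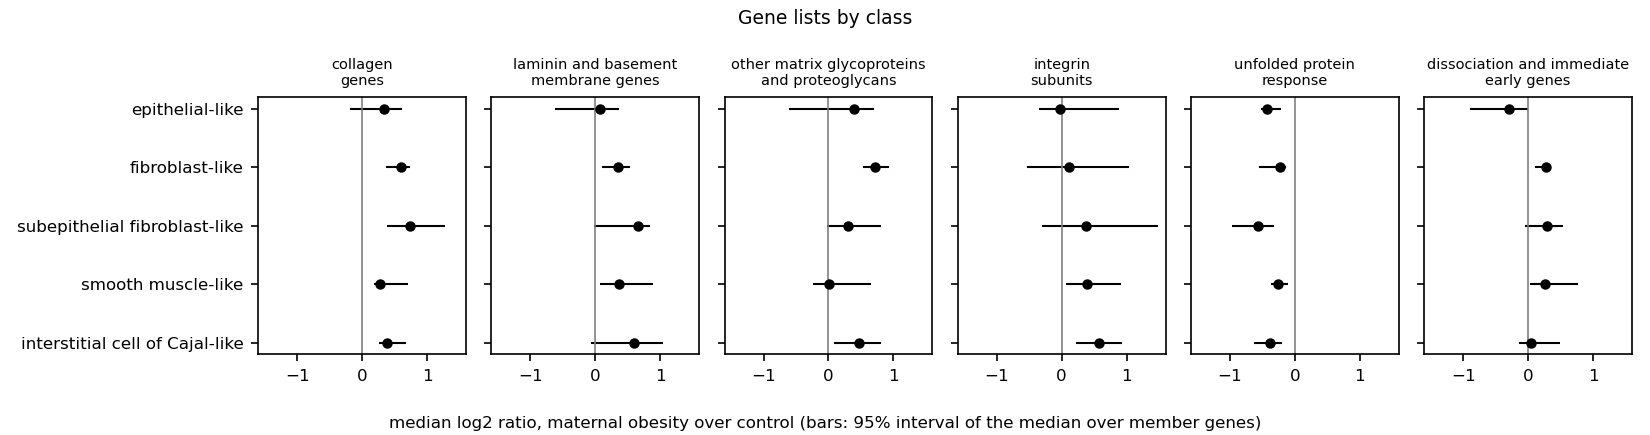
Median log2 ratio (maternal obesity over control, 1 library each) of 6 gene lists in 5 classes, with the 95% interval of the median over member genes as bars. Collagen medians run from 0.28 in smooth muscle-like to 0.73 in subepithelial fibroblast-like cells, and unfolded protein response medians lie below 0 in all 5 classes, at -0.43 in epithelial-like and -0.57 in subepithelial fibroblast-like cells.

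Unfolded protein response genes were lower on balance outside the epithelium too. Their median was -0.57 (-0.96 to -0.33; 1 higher and 8 lower of 17) in subepithelial fibroblast-like cells, -0.38 (0 and 4 of 16) in ICC-like cells, -0.26 (1 and 4 of 17) in smooth muscle-like cells and -0.22 (1 and 4 of 17) in fibroblast-like cells. Chac1, a target of the stress factor Atf4 that degrades glutathione, was among the named genes with a deficit in 4 classes: fibroblast-like (4.92-fold, 4.11 to 5.89), subepithelial fibroblast-like (17.3-fold, 11.8 to 25.9), macrophage-like (17.7-fold, 11.3 to 29.2) and erythroid-like cells (21.9-fold, 14.1 to 35.6). Atf4 was 1.80-fold lower in subepithelial fibroblast-like cells and 1.99-fold lower in macrophage-like cells. Dissociation and immediate early genes, lower in pooled epithelial-like cells, were higher in fibroblast-like (0.28; 4 higher and 1 lower of 22), smooth muscle-like (0.27; 8 and 0 of 21) and glia-like cells (0.60; 10 and 0 of 20), where Egr1 was at 207 and 634 CPM.

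Named genes of the mesenchymal classes included patterning and signalling genes. Fibroblast-like cells of maternal obesity had more of the anticoagulant receptor gene Thbd (2 and 154 UMIs, 26.8-fold, 7.29 to 223) and of the complement gene C7 (7.36-fold, 4.04 to 14.96), and less of the vessel genes Angpt2 (6.76-fold, 4.62 to 10.1) and Esam (5.09-fold, 3.83 to 6.81). The chemokine gene Ccl19 (1 and 116 UMIs, 40.3-fold, 7.10 to 1607) had 52.6% of its UMIs in 1 cell. In subepithelial fibroblast-like cells the growth factor gene Ereg (1 and 303 UMIs, 56.4-fold, 10.1 to 2235), the protease gene Mmp10 (5.42-fold, 3.303 to 9.564) and Calcb (0 and 73 UMIs) were higher, and Hoxd13 was 8.95-fold lower (4.17 to 20.1). In smooth muscle-like cells, whose clusters C12, C13 and C14 differ in share, Cyp1b1 (27.9-fold, 15.7 to 54.7), the retinoic acid enzyme gene Aldh1a2 (12.5-fold, 6.73 to 25.8) and Hoxc8 (3 and 101 UMIs, 41.8-fold, 13.9 to 206) were higher and Bhlhe22 was lower (5.91-fold, 3.22 to 11.9). Isg15 was 7.26-fold lower there with 64.7% of its UMIs in 1 cell. ICC-like cells had more Col13a1 (4.69-fold, 2.63 to 9.09), Lbh (4.51-fold, 2.63 to 8.31) and Wdr91 (4.07-fold, 2.60 to 6.67), and less of the epithelial transcripts Fam3d (6.91-fold) and Lypd8 (3.40-fold) and of S100a6 (3.00-fold).

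Enteric neuron-like cells had more of the G protein gene Gnb1 (3.76-fold, 3.06 to 4.66), the phosphatase gene Ppp2ca (3.66-fold, 2.62 to 5.23) and Zfp580 (3.21-fold, 2.49 to 4.19) in maternal obesity, and neuron genes had a median of 0.18 (3 higher and 0 lower of 19). Their named genes with a deficit were epithelial transcripts, Spink1, Pyy and Agr2, of which 72.9%, 94.7% and 37.0% of UMIs lay in 1 cell. Glia-like cells had more of the immediate early gene Egr2 (4.45-fold, 2.92 to 7.01) and the kinase gene Sik1 (5.33-fold, 3.12 to 9.71), and glia genes had a median of 0.37 (3 and 0 of 8). The other named genes of glia, Cxcl13, Dazl, Fcrla and Tuba3a, each came mostly from 1 cell.

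Among immune and blood cells, the inflammatory list had a median of -0.35 in macrophage-like cells (-0.89 to 0.045; 1 higher and 8 lower of 21, percentile 0.0). The neutrophil chemokine gene Cxcl2 was at 6956 and 3745 CPM and Ccl3 at 4062 and 1695 CPM. RT1-A1 was 28.4-fold lower (19.9 to 41.9) and Akr1b8 lower with 100 and 2 UMIs (86.3-fold, 23.3 to 723), against the excess of Akr1b8 in epithelial-like cells. The matricellular gene Spp1 was higher with 3 and 85 UMIs (16.4-fold, 5.43 to 81.2), while 74.0% of Ina and all of Cxcl9 lay in 1 cell. Lymphoid-like cells had proliferation genes at 0.59 (10 and 0 of 20) and RT1-A1 71.5-fold lower (82 and 3 UMIs, 23.6 to 354), and the other 5 named genes, Mcpt4, Mcpt1, Ahsp, Actg2 and Tagln, came mostly from 1 cell each. In erythroid-like cells Wdr91 (16.9-fold, 9.85 to 32.0) and Ifit1bl (8.42-fold, 6.01 to 12.2) were higher, Crabp1 was lower with 85.0% of its UMIs in 1 cell, and proliferation genes had a median of -1.30 (0 and 16 of 20) against the all-gene shift of -0.75.

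HOX genes, which pattern the gut from anterior (low paralog numbers) to posterior (high), differed between the libraries in both directions. In epithelial-like cells the posterior Hoxb13 was at 146.7 CPM in control and 26.1 CPM in maternal obesity (5.61-fold lower, 5.256 to 5.997), Hoxd13 was 5.70-fold (4.61 to 7.11), Hoxd11 8.32-fold (5.32 to 13.7) and Hoxa13 3.04-fold lower (2.07 to 4.55). The more anterior Hoxb3 (2.76-fold, 1.98 to 3.90), Hoxb6 (2.36-fold, 1.76 to 3.17) and Hoxb7 (1.87-fold, 1.75 to 2.01) were higher. With the 9 clusters weighted equally the log2 ratios were -2.15 for Hoxb13, -1.29 for Hoxd13, -1.12 for Hoxd11 and 0.63, with the other sign, for Hoxa13, while Hoxb3 was at 1.01, Hoxb6 at 0.95 and Hoxb7 at 0.72. After thinning, 28.4% of control and 5.54% of maternal obesity epithelial-like cells had a Hoxb13 UMI (43.8% and 10.9% unthinned), against 0.897% and 0 macrophage-like cells (limit 0.872%), while in goblet-like cells the shares were 43.4% and 40.0%. In smooth muscle-like cells Hoxd13 was 3.16-fold (2.51 to 4.00) and Hoxd12 4.45-fold lower (2.98 to 6.86), with Hoxd11 1.34-fold and the hindlimb patterning gene Pitx1 3.16-fold higher, while the anterior Hoxb4 was 1.33-fold lower (1.13 to 1.57). In fibroblast-like cells Hoxd13 was 2.16-fold (1.49 to 3.11) and Hoxd12 3.38-fold lower (2.09 to 5.51), Hoxd11 was 1.11-fold higher (0.865 to 1.44) and Hoxc8 4.69-fold higher (2.62 to 9.27). In ICC-like cells Hoxd13 was at a ratio of 1.10 (0.827 to 1.48), Hoxd12 was 1.49-fold (1.12 to 1.99) and Hoxb13 6.70-fold lower (15 and 4 UMIs, 2.14 to 27.8), and Hoxc8 was 9.79-fold (2 and 35 UMIs, 2.52 to 84.0) and Hoxd11 1.89-fold higher (1.52 to 2.38). In glia-like cells Hoxb6 was 2.04-fold (1.297 to 3.265) and Hoxd1 1.46-fold lower (1.28 to 1.68).

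**Figure D4:**
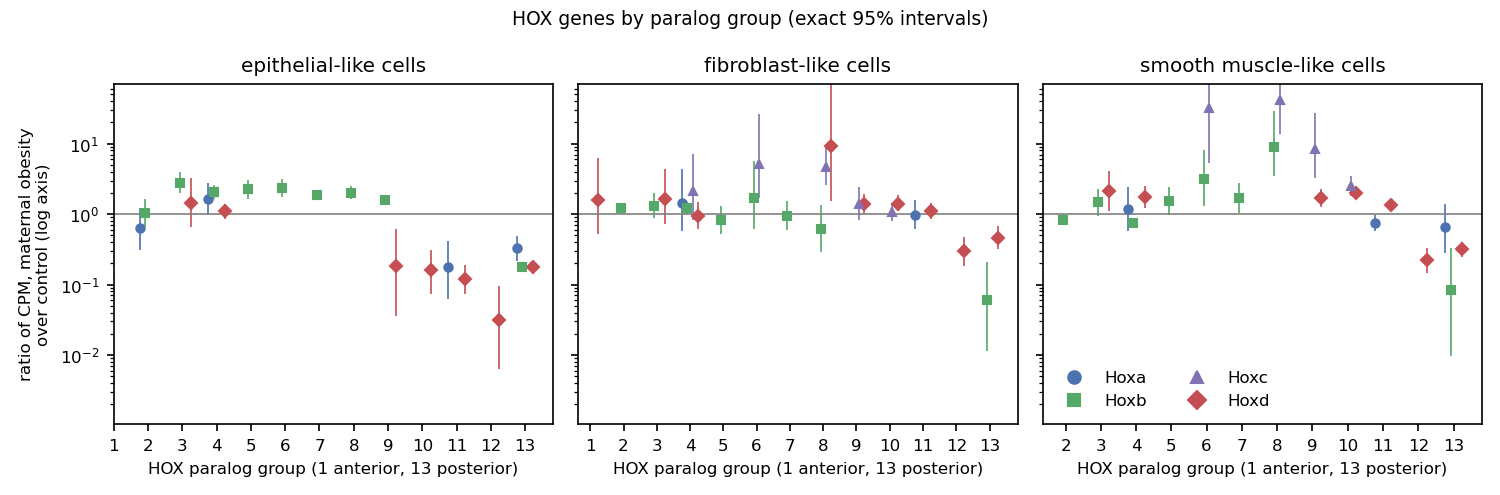
Ratio of CPM in maternal obesity over control (log axis, 1 library each) of HOX genes with at least 20 UMIs and none at 0 in either library, by paralog group from 1 (anterior) to 13 (posterior), in epithelial-like, fibroblast-like and smooth muscle-like cells, with exact 95% intervals as bars. Hoxb13, Hoxd13 and Hoxd12 lie below 1 in all 3 panels, for example Hoxd13 at 0.175 in epithelial-like, 0.464 in fibroblast-like and 0.317 in smooth muscle-like cells, while Hoxc8 lies above 1 in the mesenchymal classes.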

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

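How the left-out barcodes were counted was chosen after their values had been seen. Barcodes that the filters removed, which no comparison of classes or genes above uses, were more frequent in the maternal obesity library than in the control library in 3 respects. Left-out barcodes with most of their UMIs from haemoglobin genes made up 13.92% of all barcodes in maternal obesity (13.24 to 14.62) and 10.25% in control (9.632 to 10.9). Among all barcodes, kept ones included, 1906 in maternal obesity and 1106 in control had most of their UMIs from haemoglobin genes. Left-out barcodes above the mitochondrial limit made up 9.193% (8.626 to 9.785) and 7.099% (6.574 to 7.652). Under an earlier count restricted to barcodes with at least 500 genes, those above the mitochondrial limit made up 3.181% and 3.471%, so the excess lies in barcodes with few genes. Barcodes under the gene minimum made up 22.33% (21.5 to 23.17) and 19.26% (18.45 to 20.1). No explanation for these values was tested.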

How the results depend on the processing

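Equal weighting of epithelial clusters, removal of the highest doublet scores, addition of low-UMI epithelial clusters and the count of 12 core tuft genes were chosen after the data were seen, as was the choice to give every moved share here. No paired analysis was possible because each group holds 1 library. Of 258 values of 42 shares under alternatives, 164 stayed within the counting interval and 94 moved. Of 1201 values of 94 gene lists, 1171 stayed within the interval, 27 moved and 3 turned. A list counts as turned only where its own interval leaves out 0, and 98 of the list values, these 3 included, had the other sign. Of 384 values of 90 named genes, 292 stayed within the interval, 90 moved and 2 turned. Epithelial-like and fibroblast-like cells kept their order in 8 of 8 alternatives, at 29.4% to 41.5% and 2.91% to 6.56% in control and 17.1% to 21.6% and 9.43% to 17.5% in maternal obesity. Goblet-like and stem/progenitor-like cells kept theirs in 7 of 7, at 15.1% to 31.5% and 7.70% to 18.1% in control and 3.09% to 7.44% and 1.64% to 8.33% in maternal obesity. No tuft-like cluster was found in any of 6 reclusterings. Smooth muscle-, ICC-, neuron- and subepithelial fibroblast-like cells kept their order in 8 of 8, while glia-like cells kept theirs in 2 of 7. The moved shares and the moved values of the main lists, 100 in all, follow by setting as control and then maternal obesity, 111 other moved values are not listed, and the cause was not tested. With at least 1000 genes, epithelial-like cells were 35.7% and 17.1%, goblet-like 24.1% and 4.77%, stem/progenitor-like 12.3% in control, fibroblast-like 17.0% in maternal obesity, smooth muscle-like 14.02% and 10.5%, ICC-like 8.39% and neuron-like 7.02% in maternal obesity, macrophage-like 0.908% and 1.30%, and lymphoid-like 1.597% and 3.19%. With ComBat adjustment, epithelial-like cells were 29.4% and goblet-like 21.1% in control, stem/progenitor-like 11.5% and 1.64%, fibroblast-like 4.58% and 11.1%, subepithelial fibroblast-like 0.996% in control, ICC-like 6.75% and 12.3%, glia-like 0.205% in control and macrophage-like 4.93% and 6.55%. The epithelial goblet list was then at -1.54, and in goblet-like cells integrins were at 0.65 and laminins at 0.64, against -0.12 and -0.05. With low-UMI epithelial clusters added, epithelial-like cells were 40.7% and 20.3%, goblet-like 22.0% and 7.44%, stem/progenitor-like 9.75% and 3.89%, and the goblet list was at -1.73. Without erythroid and immune cells in the denominator, epithelial-like cells were 41.5% and 21.6%, smooth muscle-like 13.3% and 10.4%, and in maternal obesity fibroblast-like 17.5%, subepithelial fibroblast-like 6.70%, ICC-like 9.14%, neuron-like 7.39% and glia-like 4.96%, all of which follow from the smaller denominator. With a mitochondrial limit of 10%, goblet-like cells were 31.5% and 6.09%, stem/progenitor-like 7.70% and 3.60%, fibroblast-like 4.995% and 13.5%, subepithelial fibroblast-like 1.03% and 3.69%, ICC-like 6.999% and 11.4%, macrophage-like 5.18% and 6.65%, and lymphoid-like 1.66% in control. At Leiden resolution 2, goblet-like cells were 21.2% in control, stem/progenitor-like 11.9% and 4.44%, colonocyte-like 0.118% and 4.98%, fibroblast-like 2.91% and 9.43%, smooth muscle-like 13.2% and 12.8%, ICC-like 5.18% and 6.51%, and lymphoid-like 0.922% and 1.16%. Without the highest doublet scores, enteroendocrine-like cells were 1.16% and 0.243%, stem/progenitor-like 14.2% and 4.37%, and smooth muscle-like 13.1% in control. With doublets kept, stem/progenitor-like cells were 8.33% in maternal obesity, fibroblast-like 4.22% and 11.4%, ICC-like 6.77% and 11.3%, and lymphoid-like 3.03% in maternal obesity. Counting cells with at least 2 tuft markers in place of clusters gave 1.06% and 0.722%. With at least 3 cycling genes, epithelial-like cells were 45.3% and 60.4%, goblet-like 7.87% in control, stem/progenitor-like 84.3% in control and colonocyte-like 66.0% and 68.0%. Without thinning, cycling shares were 74.6% and 89.2% in epithelial-like, 39.9% and 48.9% in goblet-like, 96.0% and 96.3% in stem/progenitor-like and 95.5% and 94.2% in colonocyte-like cells, which follows from depth. Equal weighting of clusters put the goblet list at -0.28 against -1.18 and turned the inflammatory list to 0.052 from -0.38, the proliferation list to -0.023 from 0.39, Sst to 0.57 and Prg2 to 0.17. Leaving out cells rich in haemoglobin or collagen UMIs put laminins in stem/progenitor-like cells at 0.33 against 0.05. A mean over cells' CPM turned mitochondrially encoded genes in epithelial-like cells to -0.007 from 0.32. Depth limits the small classes most, since goblet-like and enteroendocrine-like cells of maternal obesity number 45 and 18.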

Other observations

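The comparison of abundant matrix genes with Col1a1 below was planned after its result had been seen, and the spread condition in the RT1 test was added after its result had been seen; the other tests were written before. Transcripts of other cell types differed between the libraries where they do not belong. Goblet genes had a median of -1.24 in enteric neuron-like cells (1 higher and 6 lower of 8). Of the 468 control UMIs of the goblet gene Agr2 there, 173 lay in 1 cell, and how far such cells carry the median was not tested. Scgb1a1, a secretoglobin gene, was 10.6-fold lower in smooth muscle-like cells (5.61 to 22.7), 12.5-fold lower in subepithelial fibroblast-like cells (6.17 to 27.1) and 23.7-fold lower in erythroid-like cells (10.1 to 68.0). In macrophage-like cells enteric neuron genes were at 2.34 (6 of 6 higher) and collagens at 1.71 (6 higher and 0 lower of 7), but 72.5% and 38.3% of the lists' UMIs in maternal obesity lay in 1 cell. Cells with a UMI of 4 Y-linked genes at 3000 UMIs made up 31.0% of control cells (1796 of 5801) and 25.6% of maternal obesity cells (1627 of 6346), while the labels give no sex.

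The goblet-like class and the epithelial cluster C1, which has Hoxb13 among its leading genes (586 control and 77 maternal obesity cells), were mostly control cells. A candidate explanation is that the libraries hold different stretches of the colon. If so, 5 posterior HOX genes should also be lower in maternal obesity in fibroblast-like, smooth muscle-like and glia-like cells. Glia-like cells had too few UMIs and gave no value, and over 9 gene and class values, 4 in fibroblast-like and 5 in smooth muscle-like cells, the median log2 ratio was -1.65 (-1.999 to -1.063 at the interval bounds), beyond the bound of -0.58. Without Hoxb13, which free epithelial RNA could bring, it was -1.11 over 7 values (-1.82 to -0.57, which just reaches the bound), while Hoxd11 in fibroblast-like and smooth muscle-like cells and Hoxd13 in ICC-like cells were not lower. A difference in sampled stretch therefore stays open beside an effect of maternal obesity on patterning, which was not tested. Each share and gene level above, in mesenchymal as in epithelial classes, is confounded with a difference in stretch.

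Collagen genes had a positive median in epithelial-like cells, and free RNA from the larger mesenchyme of the maternal obesity library could bring it. If it did, non-matrix mesenchymal genes were predicted to move by as much. The collagen median was 0.34 (17 genes) and theirs -0.33 (7 genes). The difference of 0.67 on the log2 scale lay beyond the written bound of 0.58, but its interval (-0.07 to 1.12) holds the bound. Most of the 7 are also smooth muscle genes, and smooth muscle-like cells were a smaller share in maternal obesity (8.75% against 12.1%). Des, 1 of them, was a leading gene of epithelial cluster E0. Their shift is thus no clean measure of free RNA from fibroblasts. Free RNA and epithelial expression cannot be told apart for the collagen list. The most abundant matrix genes were also compared with Col1a1. Relative to fibroblast-like, subepithelial fibroblast-like, smooth muscle-like and ICC-like cells, the lowest of them was still 6.95 times as high as Col1a1. Free RNA of these classes at the share of Col1a1 would not give such levels. The genes were picked for a high level in epithelial-like cells, which favours this outcome, and free RNA of other classes was not compared.

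RT1-A1 was lower in maternal obesity in each class with UMIs in both libraries, from 2.59-fold in glia-like to 71.5-fold in lymphoid-like cells. A variant of this region in the animals against the reference could do this, with the rest of the class I pathway unmoved and another RT1 class I gene higher. Of the 6 pathway genes, Tap2 had under 20 UMIs in each class and gave no value. The others had a median log2 ratio of 0.03 (0.026; -0.22 to 0.52 over 18 values), above the written bound of -0.58. Single values could still lie far from the median, since Psmb8 in fibroblast-like cells had 0 UMIs in control and 35 in maternal obesity. In epithelial-like cells, though, RT1-CE5 (1.53-fold), RT1-S3 (1.67-fold), RT1-CE10 (1.79-fold), RT1-CE4 (1.44-fold), B2m (1.15-fold) and Tap1 (1.345-fold) were lower too. With clusters weighted equally the log2 ratio of B2m was 0.74 (higher in 9 of 9 clusters) and that of Tap1 -0.06. Psmb8 was then at -0.25, Psmb9 at 0.32 and RT1-A2 at 0.41. The pooled deficits of B2m and Tap1 thus did not hold at equal weights. No such value is given for the RT1-CE genes and RT1-S3, so lower class I expression in epithelial-like cells stays open for them. The second condition, another gene at least 1.5-fold higher in most of 5 classes, was not met. None of 15 other RT1 class I genes was so in more than 1 class where it had at least 20 UMIs. Only RT1-CE4 (3 classes), RT1-M3-1 (4) and RT1-N3 (4) had that many UMIs in most classes, so the others could not have met the condition. Below 20 UMIs RT1-CE7, 1.53-fold higher in epithelial-like cells, was also 1.91-fold higher in fibroblast-like (2 and 11 UMIs) and 3.10-fold higher in smooth muscle-like cells (2 and 5 UMIs), with intervals that hold 1. For RT1-N3, measured in 4 classes, the intervals excluded that size in 0 of 5, so the counts are too low to decide, and a variant and a difference in RT1-A1 expression cannot be told apart.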
